A study of Homo sapiens with 2 samples.

How the data were processed

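Total RNA of COLO320 cells was labelled and hybridised to 2 two-colour Agilent 44K arrays, 1 for each CDX2 siRNA, with time-matched control RNA in the second channel, per the labels. The deposited values are log10 ratios of Cy5 over Cy3, read as such because the submitters' processing notes name Agilent Feature Extraction 9.5.3, whose log ratio is in base 10; the base itself is not written in the sources used here. They were used as deposited, after whatever background and dye correction that tool applied, which is not given in the sources used here, and were converted to log2. The direction, CDX2 siRNA over control, comes from the dyes in the labels, and the sign of CDX2 did not go against it. The deposited medians were 0 on both arrays. As deposited, 16681 features (37.1%) with siRNA 6 and 17415 (38.7%) with siRNA 8 were exactly 0, and 16311 of these on both arrays. An exact 0 was read as a ratio that was not measured, a reading that no source states, and 0 was kept as a value in an alternative. The table holds no intensities, so dim or saturated features could not be left out and signal over background is unknown.

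Of 45015 features, 31332 were paired with 1 gene, 93 with several and 13590 with none in the platform annotation, and only the first kind was used. The gene identifiers of 31291 features matched a RefSeq gene table, and 0 symbols changed. The array's genome build is not given in the sources used here, so no coordinates are printed. A gene's value is the mean of its features with a ratio on both arrays, which left 12842 genes. Of these, 7909 rested on 1 feature and 1530 had features of 2 or more accessions. Probe names are not in the tables used here, so repeat spots of a probe and different probes under 1 accession could not be told apart. In 172 accessions with 10 or more features the median SD over features was 0.0739 with siRNA 6 and 0.0791 with siRNA 8 (log2).

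Genes were tested with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), with an intercept-only fit to the 2 arrays and eBayes against 0. The fit had 1 residual degree of freedom and a prior of 2.87, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. Nothing in the labels says whether the siRNAs were transfected in separate cultures prepared independently, so p-values measure the spread between these arrays. Agreement between siRNAs was set against 1000 simulations of unchanged groups with 1 shared control, which was given the same spread as each siRNA group. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists, with alternatives by an estimated correlation, ranks, cameraPR and fry. Different probes of a gene were compared between arrays with 1 randomly chosen pair of accessions per gene, repeated 200 times, and intervals are bootstraps over genes, in Python with pandas and NumPy.

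The design, the gene and list tests and the rule for named genes were fixed before the data were examined. The comparisons between probes of a gene and the tests of technical explanations were chosen afterwards. The rule takes CDX2, the 12 genes higher and the 12 lower with the largest smaller absolute value of the 2 arrays among genes past the threshold, up to 4 members per list by the same measure, and the 3 genes of opposite sign with the widest gap among those at least 1.5-fold on both arrays. The lists, also fixed in advance, hold 713 genes in 24 groups: CDX2-linked intestinal genes, Wnt/beta-catenin targets, mitotic, DNA replication and G1/S, MYC and ribosome biogenesis, p53 target, apoptosis, interferon-stimulated, unfolded protein and amino acid stress, heat shock and oxidative stress, cholesterol synthesis, neuroendocrine, epithelial, mesenchymal and fibroblast, haematopoietic, stomach, intestinal stem and progenitor, secretory, Notch and BMP, HOX, neighbours of CDX2, glycolysis and hypoxia, small RNA pathway and housekeeping genes. List members without a tested feature were not analysed here. In the median probe alternative, a gene with an even number of features took the lower of the middle pair. Alternatives covered centring, scale, quantile normalization, the variance prior, the probe rule, a fold of 1.2 in limma's treat, the log base, fold thresholds, each array alone, and, chosen after seeing the data, the reading of exact zeros and 3 restrictions on features.

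The fit was tested on simulated data, 20 sets of 12842 genes with 200 changed. It recovered 0.475% of genes changed 1.5-fold, 26.3% of those changed 2-fold and 91.9% of those changed 4-fold, with 5.78% of calls false. Camera called a shifted list in 20 of 20 sets and 4.17% of unshifted lists at an unadjusted p under 0.05. The simulated noise was independent between arrays and genes, with no shared control or dye effect. In the data 5225 of 12842 genes passed, far more than the 200 changed here. These percentages therefore do not carry over to the calls in the data, and the camera check does not show how camera performs there.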

Results

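Gene expression was measured on 2 two-colour Agilent whole human genome arrays in COLO320, a human colorectal cancer cell line with neuroendocrine features. Cells were transfected with 100 nM of 1 of 2 different siRNAs against CDX2 (siRNA 6 and siRNA 8), or with a non-targeting control siRNA, and RNA was taken 24 h after a change of medium. CDX2 is a homeobox transcription factor of the intestinal lineage. Each array held RNA of 1 CDX2 siRNA labelled with Cy5 and control RNA labelled with Cy3, so that each ratio is CDX2 siRNA over control, and the 2 siRNAs are the replicates (n = 2 throughout). The deposited table held 45015 features, of which 27230 had a ratio other than 0 on both arrays. Ratios of 12842 named genes were tested. The number of arrays limits the precision, no array had the dyes swapped, and both arrays compared with control RNA whose own spread was not measured.

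CDX2 itself, the targeted gene, was lower with both siRNAs. Its log2 ratio was -1.44 with siRNA 6 and -1.41 with siRNA 8, with a mean of -1.42 ± 0.0192 (SD, n = 2), or 37.3% of control (limma, adjusted p = 0.00164). Its transcript stood at 37.0% of control with siRNA 6 and at 37.7% with siRNA 8. CDX2 was covered by 2 features of different accessions. The first gave 32.2% and 36.5% of control for siRNA 6 and siRNA 8, and the other gave 42.5% and 39.0%. The fall in CDX2 was not extreme among the genes tested, since its mean ratio lay at percentile 6.24 of all genes. When exact zeros of the table were kept as ratios of 0, the value of CDX2 was the same but the limma adjusted p was 0.0676, where its other alternatives with a test ran from 0.00164 to 0.003. That setting adds 5002 genes with 0 on both arrays, and so without spread, to the fit of limma's variance prior. The adjusted p there depends on those genes as well as on the values of CDX2.

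The first comparison asks which transcripts differed between cells with CDX2 siRNA and cells with control siRNA. The 12 genes that rose most on both arrays included CD93, a receptor of endothelial and myeloid cells (192-fold), ABCB11, the bile salt export pump (194-fold), SCIMP, an immune adaptor protein (183-fold), and TBR1, a T-box factor of the brain (161-fold). INHBA, which encodes the activin A subunit, was 139-fold higher, and POF1B was 142-fold higher. JHY, TBC1D29P, ZNF90, PITX1-AS1, NMRK2 and C2orf80 were between 122-fold and 194-fold higher. The genes that fell most were SLITRK6 (26.3-fold lower), OGN, a small proteoglycan (20.7-fold), CD24, a surface glycoprotein of epithelial and progenitor cells (log2 -4.32), SKAP1 (16.3-fold), HOXD8 (14.7-fold) and TSPAN8, a tetraspanin (14.1-fold). FZD8, a Wnt receptor, was 9.99-fold lower and CYP26B1, an enzyme that breaks down retinoic acid, was 9.39-fold lower. ATP6V0D2, CCDC15, SPAG17 and CRB1 were between 8.93-fold and 9.87-fold lower. The limma adjusted p of these 24 genes ran from 0.000128 to 0.00115, and the direction was the same on 2 of 2 arrays for each.

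Each of the 12 genes with the largest increases was measured by 1 feature, and for 5 of them a further feature of the gene on the array was at exactly 0 on both arrays. Among the 12 with the largest decreases, 9 rested on 1 feature, and the 2 features of ATP6V0D2 differed, at -4.26 and -2.35 (log2). Changes of 10-fold or more on both arrays were nearly all increases, with 263 genes higher and 6 lower, and CDX2 siRNA was in Cy5 on both arrays. Of the 263 genes at least 10-fold higher on both arrays, 260 had ratios from features of 1 accession, and a mean over more accessions reaches 10-fold only if it is not held down by the others. Where a feature was at least 10-fold higher on both arrays and features of another accession of its gene had ratios, those 60 other features had a median log2 ratio of -0.13, against 5.09 for the selected ones. For features at least 3-fold lower, the 162 other features had a median of -0.24.

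In all, 5225 of the 12842 genes (40.7%) passed an adjusted p of 0.05 in limma, 1556 higher and 3669 lower with CDX2 siRNA. The median log2 ratio of all genes was -0.13. With each array centred on its median, 59.9% of the genes past the threshold were lower, against 70.2% without centring. At least 1.5-fold in the same direction on both arrays were 1002 genes higher and 2366 lower, against 106 and 673 expected of independent lists of these sizes, and a mean of 45.5 and 45.9 in simulations of unchanged groups that share 1 control. The first value leaves out a control or dye effect that both arrays share, and the simulations leave out dye effects. They also assume a control with the same spread as each siRNA group, which was not estimated. With exact zeros kept as ratios of 0, limma called 0 of 18334 genes, with 5218 at an unadjusted p under 0.05, and limma's robust variance prior called 35. Of the 18334 genes, 5002 then had 0 on both arrays, and their lack of spread enters the variance prior. Limma treats the 2 siRNAs as replicates, so its p-values measure only the spread between these arrays, which leaves out the control's own spread and any dye effect.

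The second comparison asks how far the 2 siRNAs gave the same change. Across genes, which are not independent replicates, the ratios of siRNA 6 and siRNA 8 correlated with a Pearson r of 0.951 and a Spearman rho of 0.875. The sign was the same for 85.2% of genes, against 66.7% in simulations of unchanged groups that share 1 control. The covariance was 1.13, against 0.0300 in these simulations, a difference of 1.10. The simulations gave the control the same spread as each siRNA group, which by itself fixes their share of the same sign. That spread was taken from the difference between the arrays, where a shared control cancels, so the control's own spread was not estimated. Whether both arrays used the same control RNA is not stated. Part of the excess over the simulations may come from a shared control if its spread was larger than the one simulated. Genes at least 1.5-fold in opposite directions numbered 10, led by RAB3C, a vesicle GTPase (log2 -2.21 with siRNA 6 and 1.95 with siRNA 8), KCNC1, a potassium channel (-0.93 and 2.32), and GAP43, a growth cone protein (-1.86 and 0.70). None of these 3 passed the limma threshold.

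**Figure D1:**
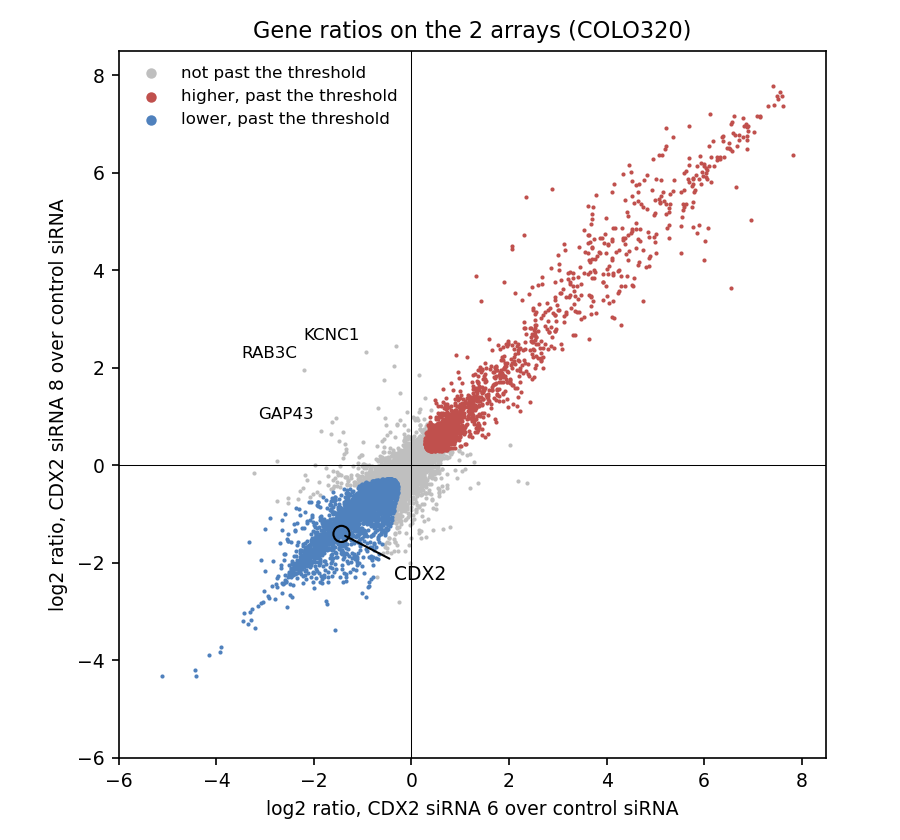
Log2 ratio of CDX2 siRNA over control siRNA for 12842 genes, with siRNA 6 on the x axis and siRNA 8 on the y axis; colours show genes past the limma threshold (adjusted p under 0.05) by direction. Points lie along the diagonal (Pearson r = 0.951), with CDX2 circled at -1.44 and -1.41 and RAB3C, KCNC1 and GAP43 named as the 3 with the widest gap among the 10 genes at least 1.5-fold in opposite directions.

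For the 1530 genes with features of 2 or more accessions, different probes of the same gene were set against each other. The ratio of 1 probe with siRNA 6 and of another probe of that gene with siRNA 8 correlated with a Pearson r of 0.0808 (95% bootstrap interval 0.0187 to 0.146), averaged over 200 random choices of probes. The same probe on both arrays gave 0.942 (0.924 to 0.955). Spearman's rho was 0.0799 and 0.873. With both probes annotated to RefSeq mRNAs, r between different probes was 0.0914 over 414 genes (95% bootstrap interval -0.0293 to 0.234). Of the 1530 genes, 17 had every accession at least 1.5-fold higher on both arrays and 64 had every accession at least 1.5-fold lower, CDX2 among the latter. Shuffling probes between these genes gave a mean of 6.34 higher (95% range 2 to 11.02) and 64.9 lower (53 to 78), so the count of lower genes is within chance pairing.

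**Figure D2:**
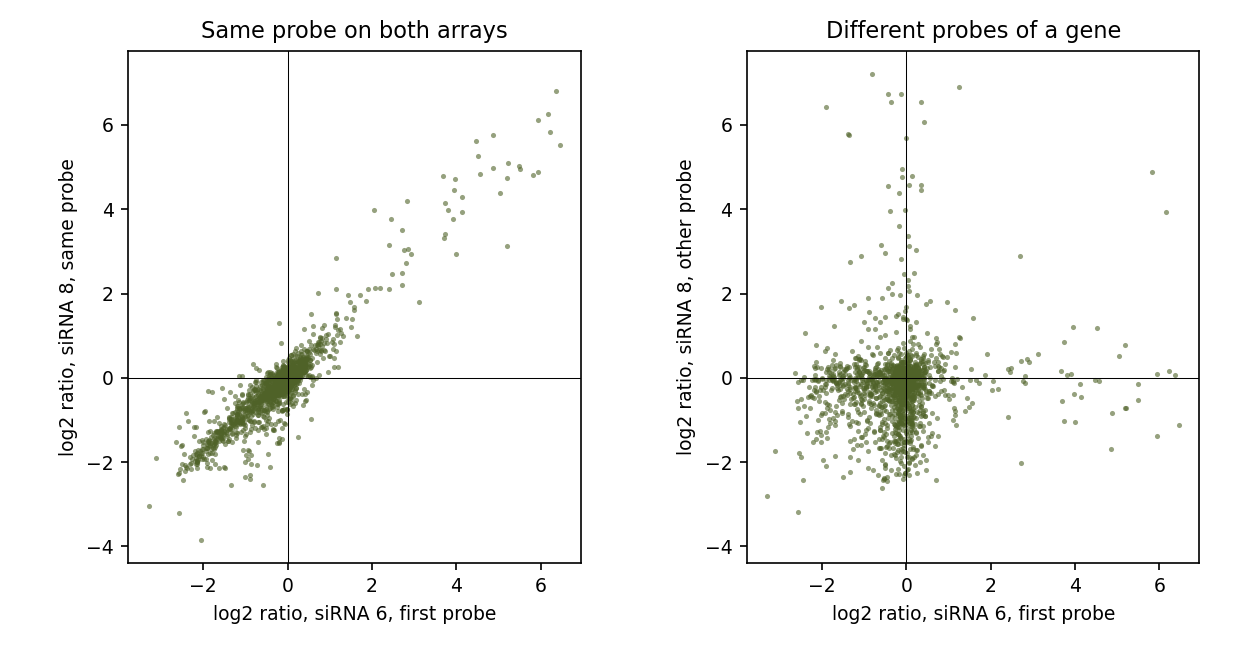
Log2 ratios of 1530 genes with probes of 2 or more accessions, for 1 random choice of probes per gene; the x axis is the first probe with siRNA 6, and the y axis is siRNA 8 for the same probe (left) or for another probe of the gene (right). Same probes follow the diagonal (r = 0.936 in this choice), and different probes do not (r = 0.0850).

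Genes fixed in lists before the data were examined were then compared with all other genes. Targets of Wnt/beta-catenin signalling, the pathway that drives intestinal crypt growth, were higher than other genes (camera, adjusted p = 0.00488). With an estimated correlation, however, the camera adjusted p was 0.839. That estimate was -0.0227 for this list and has the limit that it rests on 1 residual degree of freedom. Of 33 members tested, 15 rose, 6 fell and 12 did not pass, with the same counts adjusted over the list alone. PROX1, a homeobox factor, was 118-fold higher, MMP7, a matrix protease, 56.5-fold and NKD1, an inhibitor of the pathway, 3.56-fold, while EPHB3, an ephrin receptor of crypt cells, was 4.13-fold lower. PROX1, MMP7, NKD1 and EPHB3 each rested on 1 feature, 5 of the 33 members had features of 2 or more accessions, and the list's median log2 ratio was 0.13. PROX1 and NKD1 each had a further feature at exactly 0 on both arrays. Genes of heat shock and oxidative stress were also higher than other genes (camera, adjusted p = 0.0165), with 8 of 22 higher and 1 lower, all genes and the list alone alike. With an estimated correlation, which was -0.0130 here and has the same limit, the camera adjusted p was 0.839. CameraPR on the mean log ratio gave an adjusted p of 0.826 for this list and 0.0315 for the Wnt list. The metallothioneins MT2A (1.80-fold), MT1X (1.65-fold) and MT1E (1.52-fold) rose and MT1F fell (2.27-fold lower). The other 22 lists did not pass. Some of them passed camera under alternatives: with every feature counted on its own, the CDX2-linked intestinal, MYC, unfolded protein, mesenchymal, haematopoietic, secretory, Notch and BMP, and HOX lists; with exact zeros kept, the mitotic, DNA replication, and Notch and BMP lists; without features of 10-fold or more, the unfolded protein, Notch and BMP, and HOX lists; and the Notch and BMP list also with the median probe and with RefSeq mRNA features. Counted on their own, features of 1 gene enter as separate members, such as 10 of ABCB1 in the CDX2-linked list. They are not independent, so the calls made per feature may be too many. With exact zeros kept, 5002 genes at 0 on both arrays joined the genes that lists were compared with. Members on the array without a ratio on both arrays were not tested, and the counts cover the rest. They numbered 13 of 22 in the stomach list, 16 of 27 in the secretory, 17 of 33 in the neuroendocrine, 14 of 42 in the interferon, 11 of 30 in the mesenchymal and 9 of 19 in the haematopoietic list. A further 7 of 29 in the epithelial, 7 of 29 in the HOX, 6 of 30 in the Notch and BMP, 6 of 39 in the Wnt, 5 of 21 in the stem cell, 4 of 24 in the neighbour, 3 of 26 in the p53 and 1 of 28 in the glycolysis list had none. Where 1 pair of counts is given for a list, the counts adjusted over the list alone were the same.

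Genes linked to CDX2 in the intestine moved both ways and as a list did not pass against other genes (camera, adjusted p = 0.593). Of 14 members tested, 2 rose and 5 fell, and 3 rose and 6 fell when adjusted over the list alone, with a median of -0.33. CDH17, the liver-intestine cadherin, was 5.20-fold lower (log2 -2.38 ± 0.134, SD, n = 2) and HEPH, an intestinal iron oxidase, was 3.13-fold lower. CDHR5, a brush border protocadherin, was 17.2-fold higher and ANPEP, a brush border aminopeptidase, 10.2-fold higher. Another 21 members of this list had no feature with a ratio on both arrays. All 14 tested members were measured through a single accession. CDHR5, ANPEP and HEPH each rested on 1 of 2 features, with the other at exactly 0 on both arrays, and CDH17 rested on 1 feature.

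Other developmental groups also moved both ways. Of 22 HOX genes, 3 rose and 13 fell, and 3 and 15 when adjusted over the list alone (median -0.72; camera, adjusted p = 0.158). HOXB1 (39.6-fold) and HOXC4 (19.5-fold) were higher, and HOXD3 (4.64-fold) and HOXD8 (14.7-fold) were lower. In the Notch and BMP pathway list, 10 of 24 rose and 5 fell, with the same counts over the list alone (median 0.13; camera, adjusted p = 0.0802). HES1, a Notch target, was 4.08-fold higher and ID2, a BMP target, 2.39-fold higher, while LFNG, a modifier of Notch receptors, was 2.62-fold lower, with its 2 features at -2.20 and -0.58 (log2). Among 16 intestinal stem and progenitor genes 3 rose and 4 fell (adjusted p = 0.629), with TNFRSF19 3.63-fold higher and ALDH1A1 1.82-fold lower. Of 11 secretory lineage genes 2 rose and 5 fell, and 2 and 7 over the list alone (adjusted p = 0.556); CLCA1, a goblet cell protein, was 53.6-fold higher and FCGBP, another one, 3.09-fold lower. Of 9 stomach lineage genes 3 rose and 5 fell (adjusted p = 0.917), among them CAPN8 (10.6-fold higher), SOX2 (3.49-fold higher) and AQP5 (3.45-fold lower). HOXB1, HOXC4, HOXD3, HOXD8, ALDH1A1 and CLCA1 were each measured by 1 feature. TNFRSF19, FCGBP, SOX2 and AQP5 each rested on 1 of 2 features and CAPN8 on 1 of 3. The features of these genes not used were at exactly 0 on both arrays.

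Cell cycle genes that passed were mostly lower, as were 70.2% of all genes that passed (3669 lower among 12842 tested). The median log2 ratio was -0.11 in the mitotic list and -0.25 in the DNA replication and G1/S list, against -0.13 for all genes. Of 35 mitotic genes, 4 fell and 31 did not pass, and 0 passed in limma when adjusted over the list alone, with 9 at an unadjusted p under 0.05. NDC80, a kinetochore protein, was 1.65-fold lower, CCNB2 1.53-fold lower and CDC25C stood at log2 -0.54. The 2 features of NDC80 differed, at -1.17 and -0.27, as did those of CCNB2, at -1.16 and -0.06. PLK1 stood at -0.34, and it no longer passed with each array centred on its median. Of 35 DNA replication and G1/S genes, 10 fell and 1 rose, and 8 and 1 over the list alone. CCNE2, a G1/S cyclin, was 3.46-fold lower, RFC3 1.91-fold lower and UNG, a DNA glycosylase, 1.51-fold higher. The fall of RFC3 rests on 1 of its 2 features, at -1.78 against -0.09 (log2). Neither list passed against other genes (camera, adjusted p = 0.593 and 0.370). Among 33 MYC and ribosome biogenesis genes 1 rose and 2 fell (0 and 1 over the list alone; adjusted p = 0.489), with PES1 2.14-fold lower, although its 2 features differed, at -2.10 and -0.10 (log2).

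Stress and death genes moved in both directions. All 5 unfolded protein and amino acid stress genes that passed, of 31, were higher (adjusted p = 0.158), led by SLC7A11, a cystine transporter (3.93-fold), and NUPR1 (3.89-fold). Of 23 p53 targets 6 rose and 6 fell, 6 and 7 over the list alone (adjusted p = 0.593). SESN2 was 2.35-fold higher and CDKN1A, the p21 inhibitor, 2.08-fold lower, with features from -1.64 to -0.34 (log2). Of 29 apoptosis regulators 3 rose and 10 fell (adjusted p = 0.586); BMF was 3.60-fold higher, and BIK (5.58-fold), CASP10 (4.40-fold) and BCL2L1 (2.34-fold) were lower, although the features of BCL2L1 ranged from -1.79 to -0.17 (log2). Of 28 interferon-stimulated genes 4 rose and 12 fell (adjusted p = 0.593), with BST2 10.3-fold higher and RIGI, a sensor of viral RNA, 4.10-fold lower. Of 19 genes of small RNA pathways 1 rose and 5 fell, 1 and 4 over the list alone (adjusted p = 0.629). AGO4 was 4.20-fold lower and ADAR 4.48-fold higher, although the features of ADAR ranged from 0.11 to 6.03 (log2). NUPR1, SESN2, BMF, BIK, BST2 and RIGI were each measured by 1 feature. AGO4 rested on 1 of 2 features, with the other at exactly 0 on both arrays.

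Markers of cell types also moved both ways. Of 22 epithelial genes 7 rose and 6 fell, 7 and 7 over the list alone (camera, adjusted p = 0.489). CLDN4, a tight junction claudin, was 94.0-fold higher and EPCAM 4.21-fold lower. Of 19 mesenchymal and fibroblast genes 7 rose and 3 fell (adjusted p = 0.238), with SNAI2 11.2-fold higher and PDGFRB 3.90-fold lower. Of 16 neuroendocrine genes 3 rose and 6 fell (adjusted p = 0.593), with SEZ6 6.02-fold higher and ISL1, an endocrine homeobox factor, 1.55-fold lower. CLDN4, EPCAM, PDGFRB and ISL1 were each measured by 1 feature. SNAI2 and SEZ6 each rested on 1 of 2 features, with the other at exactly 0 on both arrays. Of 10 haematopoietic genes, which mark a cell type outside this line, 2 rose and 6 fell, 2 and 7 over the list alone (adjusted p = 0.489). CORO1A was 3.93-fold lower, from 1 feature. Members that did not pass numbered 2 of 10 in this list and 1 of 9 in the stomach list. In the housekeeping list they numbered 21 of 23 and in the MYC list 30 of 33, where 40.7% of all genes tested passed. The cause of this difference was not tested.

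Metabolic and reference groups completed the lists. Of 20 cholesterol synthesis genes 5 rose and 3 fell, 6 and 3 over the list alone (camera, adjusted p = 0.238), with MSMO1 1.88-fold higher. Of 27 glycolysis and hypoxia genes 2 rose and 5 fell (adjusted p = 0.544), with HK1 2.85-fold higher and EGLN3 lower (log2 -2.32). Among 20 neighbours of CDX2 on its chromosome arm 1 rose and 4 fell (adjusted p = 0.629), with PDX1, a pancreatic and duodenal homeobox factor, 14.2-fold higher and GPR12 4.11-fold lower. PDX1 and HK1 each rested on 1 of 2 features, with the other at exactly 0 on both arrays. MSMO1, EGLN3 and GPR12 each rested on 1 feature. Of 23 housekeeping genes 2 fell, 1 of them over the list alone (adjusted p = 0.629); POLR2A was 2.22-fold lower, with features from -1.72 to 1.90 (log2). The median, mean and camera direction of a list differed in sign for the stomach, secretory, neuroendocrine, epithelial, mesenchymal, p53, MYC, stem cell and neighbour lists, where camera compares with the other genes, whose median was below 0.

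**Figure D3:**
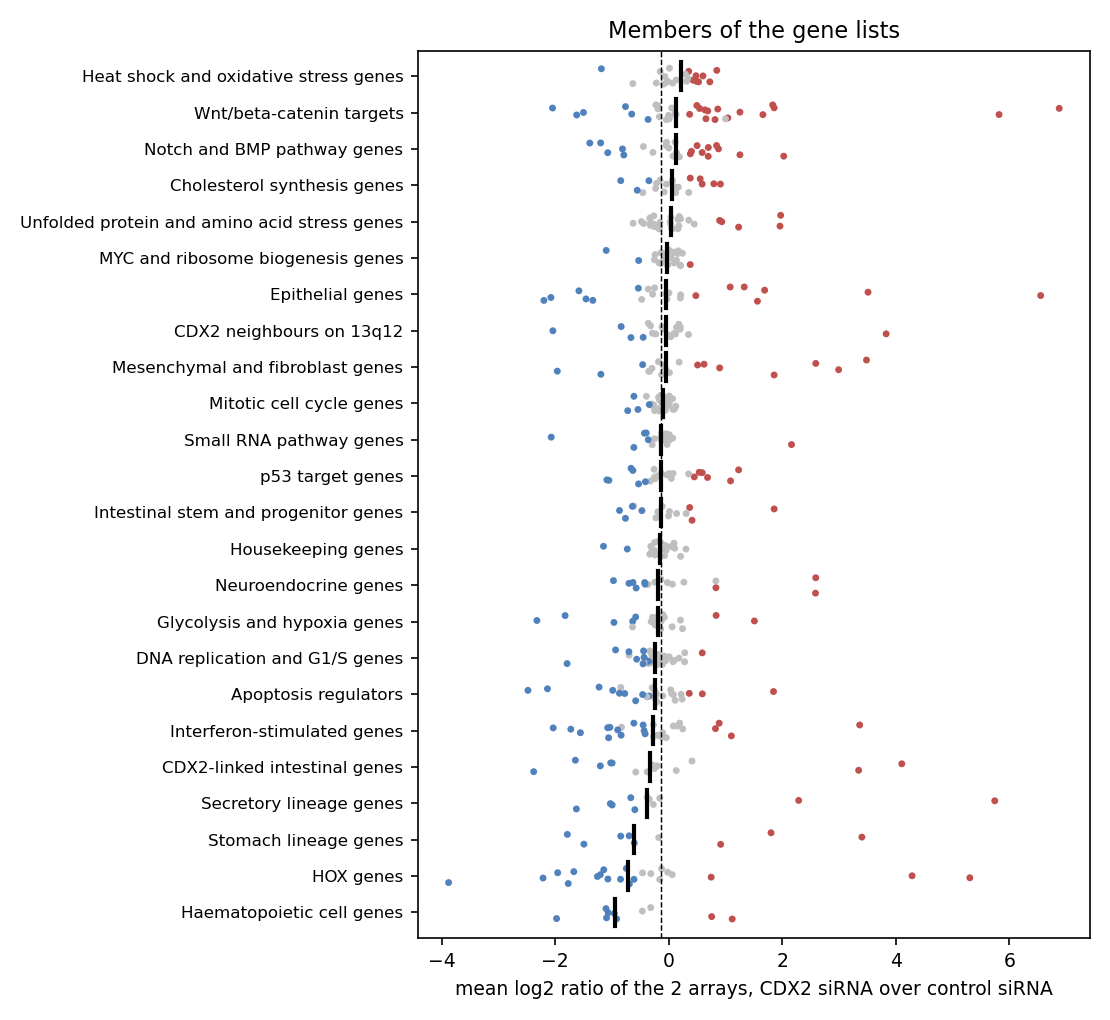
Mean log2 ratio of the 2 arrays for each tested member of the 24 gene lists (points; red, higher past the limma threshold; blue, lower past it; grey, not past), ordered by the list median (black bar). The dashed line is the median of all genes, -0.13; the highest list medians are those of the heat shock and oxidative stress genes (0.21) and the Wnt/beta-catenin targets (0.13), and the lowest is that of the haematopoietic genes (-0.94).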

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

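The alternatives on exact zeros, RefSeq mRNA features, features of 10-fold or more and genes with 2 or more accessions were chosen after seeing the data. Under the alternatives with a test, no named gene and neither list that passed camera reversed its direction. On 1 array alone, which has no test, 3 named genes (RAB3C, KCNC1 and GAP43, chosen for opposite signs on the arrays) and the medians of 3 lists (epithelial, MYC, and unfolded protein and amino acid stress) had the other sign than the mean of both, none of them past the threshold. With a test, lists that did not pass turned against camera's direction in 15 cases, none past the threshold, given here with the list's median. The stomach list turned from up to down with centred arrays (-0.50), equal spread (-0.50), per feature (-0.47), RefSeq mRNA features (-0.70), no features of 10-fold or more (-0.65) and ranks (-0.61). Per feature, the p53 (-0.22) and stem cell (-0.18) lists turned down, and with the median probe the housekeeping list (-0.15) turned up. CameraPR put the CDX2-linked intestinal (-0.33) and secretory (-0.38) lists up, and fry, which tests against 0 and not against other genes, put the MYC (-0.028), p53 (-0.14), stem cell (-0.14) and neighbour (-0.050) lists down. With exact zeros kept, the counts of genes past limma threshold, higher, and of genes past limma threshold, lower, were 0 each (0 in all; 5218 at an unadjusted p under 0.05, 35 with a robust prior), r was 0.925, 5 lists passed and CDX2 stayed at -1.42 with an adjusted p of 0.0676, where its other adjusted p ran from 0.00164 to 0.003; 5002 genes then had 0 on both arrays. Counted per feature in place of genes at least 1.5-fold on both arrays, 5280 passed, with 3782 in place of genes at least 1.5-fold on both arrays, lower, r was 0.944 and 10 lists passed. Features of 1 gene are not independent in that count. The median probe, taken as the lower of the middle pair for an even number of features, gave r = 0.943. RefSeq mRNA features gave 0.946, and absolute log2 values up to 3 gave 0.900. Without features of 10-fold or more, r was 0.901 and 5 lists passed. Read as log2, the table held 586 such genes (431 for genes at least 1.5-fold on both arrays, higher, and 155 lower), and a 2-fold threshold left 1908 (1226 lower), both by construction. Among genes with 2 or more accessions in the same direction, 445 passed limma (80 higher, 365 lower) and 279 were at least 1.5-fold (50 higher, 229 lower), from fewer genes. Of the lists, an estimated correlation, with 1 residual degree of freedom, called 0 (0 at an unadjusted p under 0.05), and fry 0 (5 at an unadjusted p under 0.05). CameraPR called 1, the Wnt/beta-catenin list, and the heat shock and oxidative stress list lost its call (cameraPR, adjusted p = 0.826). For the rest, the cause was not tested. Each array alone gave 3966 to 4259 genes of at least 1.5-fold (1154 to 1182 higher, 2784 to 3105 lower), and CDX2 from -1.44 to -1.41. Over named genes and alternatives with a test, 1037 values kept direction and side of the threshold, 136 lost the call, 115 of them with exact zeros kept, and 5 gained it. Limma's count without a replicate was not run, since 1 array leaves no residual degrees of freedom, nor were a filter on dim features or genes measured on 1 array, which the table or the test does not allow. No paired analysis was possible because there is 1 group, and each ratio already sets it against control RNA on the same array. Signal over background is unknown, so it cannot be said which ratios rest on dim features.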

Other observations

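The tests on a shared control, on the joining of values to features, on genes whose probes moved together and on the share of other probes past 1.5-fold were chosen only after their results, or values close to them, had been seen, as were the genes named in the next paragraph.

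Some genes were measured by probes of 2 or more accessions that all moved at least 1.5-fold one way on both arrays. Ranked by the smallest change of any probe on either array, the first of 17 upward genes were DNAH6, a dynein of cilia (mean log2 5.32), C11orf21 (4.72), AHNAK, a giant scaffold protein (2.84 over accessions), and LINC00963 (1.60). By the same measure the first of 64 downward genes were WNT5A, a non-canonical Wnt ligand (-2.73), SPAG6, a sperm and cilia protein (-2.39), MFSD2A, a lipid transporter (-2.14), and SHC3 (-2.21), with CDX2 at -1.42. When probes were shuffled between the 1530 genes 1000 times, 2 to 11.02 genes had all probes up and 53 to 78 had all probes down (95% ranges). The 17 upward genes exceed chance pairing and the 64 downward genes do not. Over both directions, 81 genes stood against 58 to 85. A hypothesis is that some of the upward genes changed as whole transcripts, but dye effects that act on several probes of a gene were not tested.

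Very large ratios at single probes. For 50 genes with a feature at least 10-fold higher on both arrays, 60 probes of other accessions had a median log2 ratio of -0.1274 (95% interval -0.32 to 0.066), against -0.10 for all named features. For features at least 3-fold lower, the other probes stood at -0.242 (-0.41 to -0.10), an interval just below the value of all named features but not below the -0.15 of all probes of genes with 2 or more accessions. Both medians lie near what signals specific to single probes predict. Of the other probes, 18.3% (8.33% to 29.2%) were nevertheless at least 1.5-fold higher too. Among all probes of genes with 2 or more accessions the share was 7.63%. The interval lies above that share, so part of the increases may have been shared between probes, although its lower bound is close to the share. Where both probes of a gene were selected, as for DNAH6 and C11orf21, each counts as an other probe. For decreases the shares were 31.5% (24.2% to 39.1%) and 26.3%. Genes without another measured probe, such as CD93, ABCB11 and CLDN4, are not covered. A dye effect remains open, since no array had the dyes swapped. Cross-hybridisation, a probe that reads another transcript form and a change of a transcript isoform with CDX2 knockdown were not tested and also remain open.

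The similarity of the 2 siRNAs. The arrays correlated at 0.951 across genes, yet different probes of a gene correlated at 0.0808, against 0.942 for the same probe. If the gene names are right, control RNA that differed for a gene would be seen by all its probes, and so would a knockdown response common to them, and the upper bound of 0.1461 on their correlation (0.234 for RefSeq mRNA probes) argues against both as the main source of the similarity. Values joined to the wrong features are argued against by 172 accessions with 10 or more features, which deviated by a median of 0.0347 against 0.264 for features drawn at random. These features may be spots of 1 probe, so wrong gene names of single probes stay open, and for 3087 accessions with 2 features the correlation between the features was 0.149. A property of probes that both arrays share, such as a dye effect, may also be the source, and changes of single isoforms stay open.

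Wnt/beta-catenin targets. The list stood above other genes, and without its 2 members at least 10-fold higher the camera p was 0.002319 (median 0.11), which argues against those members as the whole source. Camera with an estimated correlation gave a p of 0.147 for the full list, but that estimate rests on 1 residual degree of freedom and cannot decide. Signals specific to single probes cannot be told apart from a change of these genes, because only 1 member that rose (AXIN2, lowest probe at 0.30) had probes of 2 or more accessions. A rise of these genes after CDX2 knockdown stays open and untested.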
